A study of Mus musculus with 12 samples.

How the data were processed

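RNA from mouse bone marrow-derived macrophages was measured on 12 Illumina bead arrays, 1 array per sample, in 4 groups of 3. The groups were cells given PBS without LPS, PBS with LPS, HDL with LPS and cyclodextrin with LPS. Groups and replicate numbers were taken from the sample labels. The labels write the HDL group as nHDL without spelling out the n, so it is called HDL here. Per the labels' protocols, HDL was given at 300 ug/ml for 24 h or cyclodextrin at 4% for 4 h, the cells were washed, and LPS was given at 10 ng/ml for 6 h. No label says that the replicates came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical.

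The authors exported the probe signals and detection p-values with GenomeStudio, per the submitters' processing notes, which give no version. The deposited tables hold a non-normalized signal per probe (another unit than an intensity as stored, explained next), a detection p-value beside it per the file headers, and a table of the authors' processed values of the same arrays. The name of the first table calls its values non-normalized. The normalization of the authors' processed values is not given in the sources used here. Each column of that table shares about 98.0% of its digit strings with the first column, as columns do after quantile normalization. The columns have a median of 73.7 once rebuilt, on a linear scale, and no centring was seen.

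In both deposited tables most values had lost their decimal mark, so the digits were known and the decimal place was not. Of the 543372 values of the non-normalized table, 10998 (2.02%) kept their point. A further 418808 (77.1%) were placed from the detection p-value or the number of digits. Another 111674 (20.6%) were placed by a curve. On each array the authors' processed value rises with the non-normalized signal, and the place taken was the 1 that put both digit strings on that array's curve. The remaining 1892 took the place of the same string or of the same probe on other arrays. As a test, 5133 values with a known place were hidden and placed again, and 0 came out wrong. All had a detection p of 0 and were placed again by the curve or by other arrays. The test therefore does not cover the 77.1% placed from the detection p-value or the number of digits. The placing rule was adjusted while this test was being looked at, so its 0 errors are not an independent error rate. Among the values placed by the curve or by other arrays, 1 lay about 10-fold from both other arrays of its group. Values placed in other ways were not checked for this. The planned design assumed intensities with their decimal mark. The planned test was kept and run on the rebuilt linear intensities.

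Signals were background corrected and quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with detection p-values in place of control probes and an offset of 16, and put on the log2 scale. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays. Gene names came from the platform annotation given for this work, with symbols checked through Entrez numbers. Of 45281 probes, 34885 had 1 symbol, 18 had several and 10378 were not listed with a gene. The reference held 34807 of the Entrez numbers and changed 0 symbols. The filter kept 18364 probes, of which 15497 had 1 symbol. Each gene was represented by its probe with the highest mean over the arrays, which left 9795 genes, 3838 of them with at least 2 passing probes. Decimal places were rebuilt in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

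A single limma model over all 12 arrays was fitted (lmFit and eBayes, two-sided, 8 residual and 6.06 prior degrees of freedom). Its 4 comparisons were LPS against no LPS in PBS cells, HDL against PBS under LPS, cyclodextrin against PBS under LPS, and cyclodextrin against HDL under LPS. All adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment over the 9795 genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error. Where a gene's probe was above background on none or only some of the arrays of the dimmer group, a called fold is given as a lower bound. For groups detected on some arrays this was decided after the values were seen, and genes were still picked and tested by their fitted fold. It sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal of any probe above background. Where that bound is under 1, or where the probe was above background in neither group, no fold is given. List medians with genes at their bound set only the genes detected on no array of 1 group to it. Counts of arrays that detected a gene are those of the same probe. For genes with several probes, the calls of each probe were adjusted over the probes with 1 symbol. The number of arrays limits the precision of every value.

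The samples, groups, tests, first alternatives, rule for naming genes and 30 gene lists were fixed before the data were examined. The lists cover cholesterol synthesis, LXR targets, fatty acid synthesis, and cholesterol efflux and storage. They cover inflammatory cytokines, chemokines, inflammatory effectors, NF-kB pathway feedback, type I interferon-stimulated genes, anti-inflammatory resolution, alternative activation and TLR signalling. They also cover ER stress, the ATF4 amino acid response, NRF2 oxidative stress, heat shock, glycolysis and hypoxia, mitochondrial respiration, lysosome and phagosome, the cell cycle, the PKC family and macrophage identity. The last ones hold markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells and basophils, erythroid cells and megakaryocytes, and fibroblasts. Of the 30 lists, 1 is not described here, though it stays in the counts of lists and in the adjustment. The 25 lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry stand beside it. The genes named in each comparison are the 5 highest and 5 lowest fold changes among called genes whose 2 groups did not overlap, leaving out symbols that are only clone, locus or model names. To these come up to 4 called members of each list with the largest change, or 2 members as values where none was called. The rule also always takes Il6, Il12a, Tnf, Il1b, Il10, Nos2, Cxcl10, Ifnb1, Atf3, Irf1, Abcg1, Insig1 and Srebf2. Another 6 genes of that last set are not analysed here.

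The model was tested on simulated data built from these arrays, with 200 of the 9795 genes changed. Among the genes changed 2-fold it recovered 98% for LPS, 98% for HDL, 97% for cyclodextrin and 96% for cyclodextrin against HDL. Among the genes changed 1.4-fold it recovered 31%, 28%, 32% and 32% in the same order, with 7, 5, 9 and 8 false calls and 0 calls of the wrong sign. Camera recovered the 1 shifted list and called 0 others. The noise in these tests was normal, independent between genes and of the model's own spread. The false calls therefore leave out what correlation between genes adds. Unchanged treated groups against the same PBS arrays were simulated in 100 draws, with the correlation between genes kept, to show what sharing those arrays gives by chance. Alternatives covered the background correction, the normalization, the authors' processed values, the detection filter, the choice of probe, the arrays in the fit, the variance model, array weights, a 2-fold threshold, the list test, and leaving out each array in turn. Alternatives on the decimal places and on the share of detected probes were added after seeing the data. The arrays' slides are not given in the sources used here, so slide was not used as a block.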

Results

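Gene expression was measured in mouse bone marrow-derived macrophages under LPS, a bacterial cell wall component, after prior contact with HDL or with cyclodextrin. HDL is the lipoprotein that takes up cholesterol from cells, and cyclodextrin is a ring of sugars that also extracts cholesterol. Each of the 4 groups had 3 arrays. Among probes on the array, 37.2 ± 1.25% (SD, n = 3) were detected above background in PBS cells without LPS, 36.7 ± 0.265% with LPS, 36.0 ± 0.173% with HDL and LPS, and 34.3 ± 0.963% with cyclodextrin and LPS. The share on every cyclodextrin array lay below that on every HDL array, and the share on every HDL array below that on every PBS LPS array (two-sided exact permutation p = 0.1 each, the smallest that 3 against 3 arrays allow). Arrays of 1 group correlated across genes at r = 0.989 to 0.996, LPS arrays of different groups at 0.985 to 0.993, and arrays with against without LPS at 0.858 to 0.883. The first principal component carried 86.3% of the variance and separated the arrays with LPS from those without. All fold changes below compare 3 arrays with 3. No contact time is given for PBS, and the same PBS LPS arrays stand against 24 h of HDL and 4 h of cyclodextrin. Contact time and handling therefore cannot be told apart from the compound in the comparisons with PBS.

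LPS switched the macrophages to an inflammatory and interferon program and lowered genes of cell division. Genes of lipid synthesis were lower too, but as lists they did not keep their call with an estimated correlation (adjusted p = 0.0721 and 0.0879). Among the highest were Acod1, which makes the antimicrobial metabolite itaconate, at least 905-fold higher (adjusted p = 1.22e-17), the chemokines Cxcl10, at least 881-fold, and Ccl5, at least 664-fold, the activation marker Cd69, at least 692-fold, and the cytokine Il1b, at least 508-fold. In PBS cells without LPS, Cxcl10 and Il1b were detected on 1 of 3 arrays and Ccl5 and Cd69 on 2 of 3. Among the lowest were Cdca7, at least 26.5-fold lower, Rasgrp3, at least 29.7-fold lower (detected on 1 of 3 LPS arrays), Sesn1 (log2 fold change -4.99 ± 0.15 SE), Zfp36l1 (-4.51 ± 0.18) and Fam214a, at least 14.9-fold lower. In all, 5932 of 9795 genes were called, 2172 higher and 3760 lower, and 1058 and 1196 of them changed at least 2-fold.

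The inflammatory groups described here rose under LPS. Of 16 genes in the inflammatory cytokine list, 14 were higher and 0 lower (camera adjusted p = 6.21e-12). The list's largest changes were in Edn1, the gene of the vasoconstrictor peptide endothelin-1, at least 166-fold higher, and Il1a, at least 157-fold. Il27 was at least 72.4-fold and Il6 at least 25.5-fold higher. Tnf was higher by 4.83 ± 0.16 on the log2 scale. Il12a was detected on 0 of 3 PBS arrays and 1 of 3 LPS arrays, so no fold is given. Of 16 chemokines 15 were higher and 0 lower, among them Cxcl9, at least 65.9-fold, and Cxcl2, at least 31.2-fold (detected on 1 of 3 PBS arrays) (1.74e-11). The inflammatory effectors rose in 18 of 19 cases and fell in 0 (1.17e-16), with Saa3 at 8.75 ± 0.11 and Nos2, the inducible nitric oxide synthase, at least 60.8-fold higher (detected on 1 of 3 PBS arrays). All 15 NF-kB feedback genes were higher (1.65e-13), led by Traf1 (5.85 ± 0.16) and Nfkbiz (5.26 ± 0.14). All 26 type I interferon-stimulated genes were higher (1.49e-23), among them Oasl1 (7.88 ± 0.13) and Mx2 (7.44 ± 0.15). Irf1 was higher by 3.19 ± 0.12, and Ifnb1, the interferon-beta gene, was at least 5.82-fold higher. Anti-inflammatory genes rose in 13 of 15 cases and fell in 1 (1.50e-10), with Socs3 at 8.13 ± 0.15, Il10 at 4.96 ± 0.16 and Dusp2 at 3.65 ± 0.12. TLR signalling genes were higher in 16 of 19 cases and lower in 2 (1.73e-06), with Tlr2 at 4.37 ± 0.12. Atf3 was higher by 0.93 ± 0.16. In each of these lists the same numbers of genes were higher and lower adjusted over the list alone. Each of the 7 lists kept its call with an estimated correlation, at adjusted p from 0.000245 to 0.0137.

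Cell cycle genes fell together under LPS, 17 of 20 lower and 0 higher, with Cdc20 at -2.94 ± 0.15 and Bub1b at -2.82 ± 0.12 (camera adjusted p = 4.33e-07, and 0.00792 with an estimated correlation). Cholesterol synthesis genes were lower in 15 of 18 cases and higher in 0, with Stard4 at -2.11 ± 0.19 and Mvd at -1.78 ± 0.15 (camera adjusted p = 0.000892, but adjusted p = 0.0721 with an estimated correlation). Fatty acid synthesis genes were lower in 10 of 13 cases and higher in 0, with Elovl6 at -3.00 ± 0.15 and Scd2 at -2.63 ± 0.24 (0.00272, but adjusted p = 0.0879 with an estimated correlation). Srebf2, the sterol regulator's own gene, did not pass (-0.17 ± 0.14, adjusted p = 0.325), nor did the cholesterol exporter Abcg1 (-0.23 ± 0.18, adjusted p = 0.288). The other probe of Srebf2 was called lower (-0.34). The probe used for Insig1 was lower (-0.42 ± 0.15) while another of its 3 probes was higher (0.99). For these 3 lists too, the counts adjusted over the list alone were the same.

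A further list called under LPS is not described here. The other 14 tested lists did not pass under LPS (camera adjusted p from 0.0946 to 0.972). Of 13 alternative activation genes 3 were higher and 8 lower, among them Pparg (-3.21 ± 0.11) and Egr2 (-1.87 ± 0.14). Of 18 ER stress genes 1 was higher and 10 lower, with Herpud1 at -2.26 ± 0.12. Of 17 ATF4 genes 4 were higher and 6 lower, of 16 NRF2 genes 3 and 6, and of 17 mitochondrial genes 1 and 7. Of 13 cholesterol efflux and storage genes 4 were higher and 4 lower, among them Ch25h (6.70 ± 0.13), and of 10 LXR targets 2 and 4. Of 14 macrophage identity genes 6 were higher and 2 lower, with the Fc receptor Fcgr1 at 3.32 ± 0.15. Heat shock genes were higher in 2 of 13 cases, Hspa1a (2.64 ± 0.14) among them, and lower in 2, glycolysis genes in 4 of 15 and 4, and lysosome genes in 2 of 18 and 5. Dendritic cell genes were higher in 3 of 5 cases and lower in 1, neutrophil genes in 2 of 6 and 1, and B cell genes in 0 of 5 and 0. Of the lists too short to test, the PKC list had 1 of 4 genes higher and 3 lower. Of 3 mast cell and basophil genes 1 was higher (Hdc, at least 136-fold) and 1 lower (Kit, at least 3.67-fold). In the fibroblast list 2 of 3 genes were higher (Lox, at least 4.88-fold, and Dcn, at least 1.41-fold). Prf1 (0.30 ± 0.14) and Pf4 (-0.01 ± 0.13), the only measured T and NK cell and megakaryocyte genes, did not pass.

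The 2 PBS groups did not overlap in 65.2% of genes, against 10% by chance. Here and below, the 10% is only the expected share. Genes on an array are correlated, and how far the share strays from 10% between unchanged groups was not measured. The split into higher and lower depends on the normalization, with 3101 higher and 2769 lower after median scaling against 2172 and 3760 here, and median scaling moved the median of all genes from -0.14 to 0.05. Of 47 called genes named by the rule with several probes, 40 had all of them called, and Cd69 had another at 0.19. The other probes of Fam214a (-0.92) and Nos2 (1.06) were called with much smaller changes than the probes used.

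Against the PBS LPS arrays, genes of fatty acid and cholesterol synthesis were lower after HDL, and a set of inflammatory cytokines was higher. Scd1, the desaturase that makes monounsaturated fatty acids, was 15.4-fold lower (log2 fold change -3.94 ± 0.16, adjusted p = 4.82e-09). The desaturase Fads2 was 3.31-fold lower (-1.73 ± 0.14, 1.94e-05), Scd2 2.43-fold lower (-1.28 ± 0.24, 0.0177) and Acss2, which makes acetyl-CoA from acetate, 2.38-fold lower (-1.25 ± 0.15, 0.00182). The highest were Tnfsf15, a TNF family cytokine, at 2.58-fold (1.37 ± 0.13, 0.000226), the chemokine Ccl17 at 2.53-fold (1.34 ± 0.19, 0.00445), the growth factor Hbegf at 2.14-fold, the protease Htra4 at 2.10-fold and the plasminogen activator Plau at 2.09-fold.

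**Figure D1:**
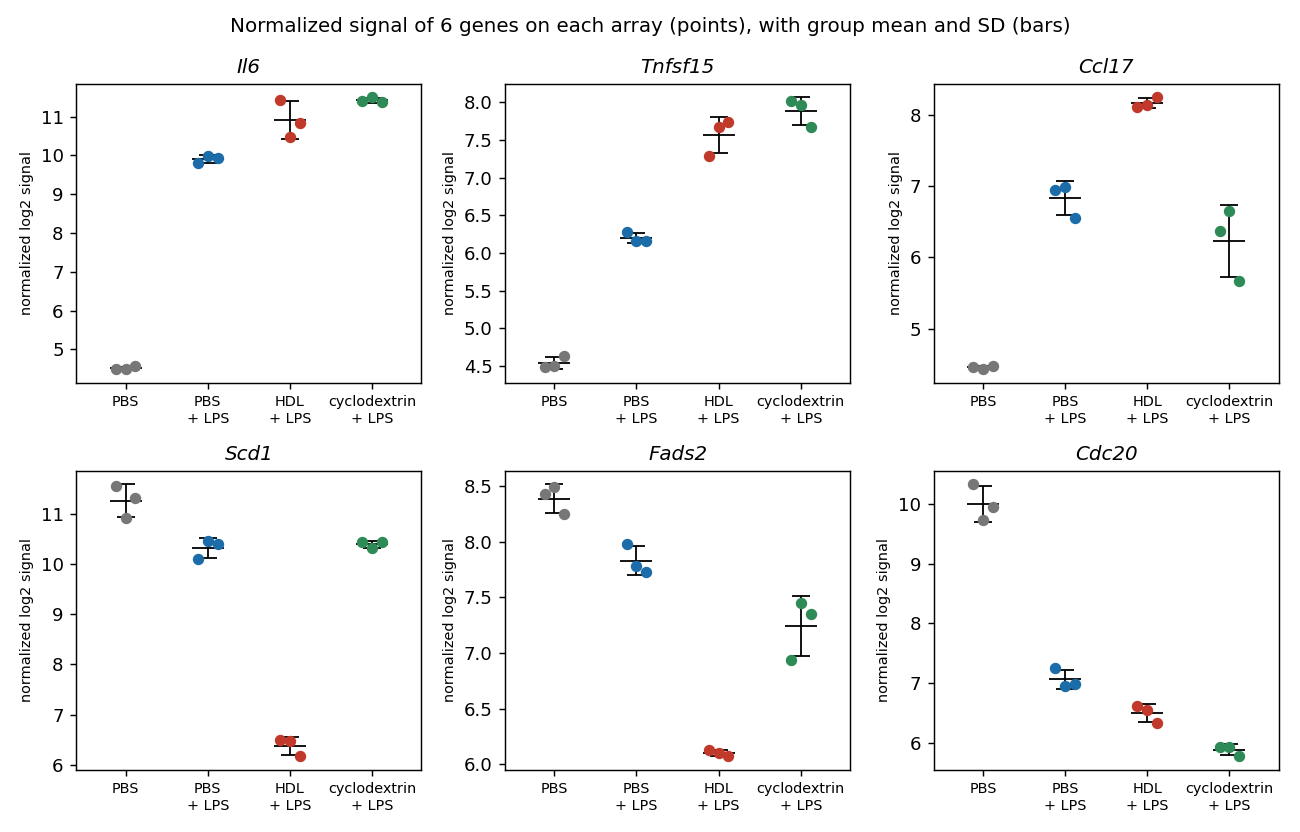
Normalized log2 signal of 6 genes on each of the 12 arrays, with points for single arrays and bars for the group mean and SD (n = 3). Scd1 was at 6.38 ± 0.18 on the HDL arrays against 10.32 ± 0.19 on the PBS LPS arrays and 10.39 ± 0.06 on the cyclodextrin arrays, and Il6 was at 9.91 ± 0.10 with PBS and LPS, 10.91 ± 0.49 with HDL and 11.42 ± 0.07 with cyclodextrin.

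Of 13 fatty acid synthesis genes, 8 were lower under HDL and 0 higher, and the same numbers adjusted over the list alone (median log2 fold change -0.62, camera adjusted p = 1.71e-14, and 0.004 with an estimated correlation). Of 18 cholesterol synthesis genes, 6 were lower and 0 higher, and 17 were lower adjusted over the list alone (median -0.54, camera adjusted p = 1.71e-14, and 0.004 with an estimated correlation). Among them were Tm7sf2 (-1.17 ± 0.13), Fdps (-0.89 ± 0.11) and Mvd (-0.69 ± 0.15). Lss was lower (-0.93 ± 0.14) by its brightest probe and at 0.30 by its other probe. LXR targets, which sterols activate, were lower in 4 of 10 cases and higher in 0, and lower in 4 and higher in 1 adjusted over the list alone (median -0.25, camera adjusted p = 0.00321, but adjusted p = 0.353 with an estimated correlation). These 4 were Scd1, Abcg1 (-0.84 ± 0.18), Lpcat3 (-0.81 ± 0.12), which inserts polyunsaturated fatty acids into phospholipids, and Apoe (-0.53 ± 0.12). Abcg1 was also the only called gene of the 13 for cholesterol efflux and storage. Insig1 (-0.50 ± 0.15, adjusted p = 0.105) and Srebf2 (0.02 ± 0.14, 0.961) did not pass.

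Of 16 inflammatory cytokines, 4 were higher under HDL and 0 lower, and 8 were higher adjusted over the list alone (median 0.39, camera adjusted p = 7.54e-09, and 0.00595 with an estimated correlation). Besides Tnfsf15 these were Il12a (at least 1.94-fold, detected on 1 of 3 PBS LPS arrays), Il6 (2.00-fold, 1.00 ± 0.18) and Il1a (1.62-fold, 0.70 ± 0.13). Tnf (0.34 ± 0.16, adjusted p = 0.275), Il1b (0.49 ± 0.14, 0.0995), Il10 (-0.28 ± 0.16, 0.369), Nos2 (0.41 ± 0.18, 0.236), Cxcl10 (0.01 ± 0.28, 0.988), Ifnb1 (0.32 ± 0.15, 0.299), Atf3 (0.50 ± 0.16, 0.116) and Irf1 (0.03 ± 0.12, 0.919) did not pass. Cxcl10 lay at 15.18 to 15.35 on the PBS LPS arrays, at the top of the named genes, so a rise may not show. Its SE reflects mainly the PBS arrays without LPS (6.05, 4.61 and 4.53). Of 16 chemokines, Ccl17 and Cxcl2 (1.01 ± 0.23) were higher and 0 lower. The anti-inflammatory list had a median of -0.18 (camera adjusted p = 0.0305, but adjusted p = 0.432 with an estimated correlation), with 1 of 15 genes called, the cytokine signalling inhibitor Socs1 (-0.51 ± 0.12). Adjusted over the list alone, 3 were lower and 1 higher, and the list's adjusted p was 0.239 with the share of detected probes as a covariate, a fit chosen after seeing the data, and its call ended in 5 of 26 settings. The other 20 tested lists did not pass (adjusted p from 0.251 to 0.997). Among 20 cell cycle genes 3 were lower and 0 higher, and 4 lower and 1 higher adjusted over the list alone (median 0.02). The 3 were the mitotic genes Plk1 (-0.77 ± 0.15), Bub1b (-0.52 ± 0.12) and Aurkb (-0.49 ± 0.11). The mitotic motor gene Kif2c, named by the rule only under cyclodextrin, was called lower under HDL too. Kif23 (-0.73), Kif22 (-0.64), Kif18b (-0.53) and Cenpn (-0.46), picked after their values were seen, were also called lower under both treatments. Top2a and Mcm3 went the other way under HDL without a call. Other called members were the hypoxia gene Ndrg1 (-0.77 ± 0.10), the glutathione transferase Gsta3 (0.72 ± 0.13), the MHC class II regulator Ciita (at least 1.48-fold higher) and the actin-bundling gene Fscn1 (0.84 ± 0.16). Troap, a mitotic spindle gene, was at least 2.08-fold lower by 1 probe and at 0.09 by its other probe. None of the 12 genes in the 5 lists too short to test was called, for example Prkcb at 0.23 ± 0.12 and Prf1 at -0.46 ± 0.14.

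In all, 186 genes were called between HDL and PBS, 78 higher and 108 lower, and 11 and 9 of them changed at least 2-fold. Simulated unchanged HDL groups gave at least as many calls in 2 of 100 draws (highest 956) and 0 calls in the others. The 2 groups did not overlap in 26.0% of genes, against 10% by chance. The count fell to 40, 36 and 87 without PBS LPS replicates 7, 8 and 9, to 67, 88 and 56 without HDL replicates 16, 17 and 18, and to 88 without PBS replicate 3, and it was 80 with only the 2 groups in the model, 102 without a detection filter, 283 without background correction, 282 with normexp and 575 with array weights. Of the 29 called genes named by the rule, 17 lost their call without at least 1 array, among them Il6 without PBS LPS replicate 7 or 8 (adjusted p up to 0.0774), Il12a without replicate 7 (0.0506), Cxcl2 in 7 of 12 omissions (0.152) and Socs1 in 11 (0.177). Of 9 such genes with several probes, 3 had all of them called, and the other probe of Fads2 lay at -0.57.

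Against the PBS LPS arrays, inflammatory cytokines and genes of the oxidative stress response were higher after cyclodextrin. Genes of cell division and of sterol and fatty acid synthesis were lower. Cdkn1c, an inhibitor of cell division, was 3.56-fold higher (log2 fold change 1.83 ± 0.13, adjusted p = 1.48e-05), the matrix protease Mmp2 at least 3.13-fold (detected on 2 of 3 PBS LPS arrays), Tnfsf15 3.21-fold (1.68 ± 0.13), the neutrophil-attracting chemokine Cxcl1 2.94-fold (1.56 ± 0.28) and the cystine transporter Slc7a11 2.89-fold (1.53 ± 0.17). Among the lowest were the adenosine receptor Adora3, at least 2.71-fold lower (detected on 1 of 3 cyclodextrin arrays), and the mitotic motor genes Kifc1, at least 2.31-fold lower, Kif11, at least 1.94-fold lower, and Kif2c, at least 2.79-fold lower (detected on 2 of 3). Troap was at least 1.92-fold lower by 1 probe and at 0.03 by its other probe.

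Of 16 inflammatory cytokines, 10 were higher under cyclodextrin and 1 lower, and 12 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 2.94e-10, and 0.00916 with an estimated correlation). Il12a was at least 2.72-fold higher (detected on 1 of 3 PBS LPS arrays), Il6 2.84-fold (1.51 ± 0.18), Tnfsf9 1.76-fold (0.82 ± 0.18) and Tnf 1.51-fold (0.59 ± 0.16, adjusted p = 0.0467), and Ebi3, named after its value was seen, was lower (-0.46 ± 0.12). Among 16 chemokines Cxcl1, Cxcl2 (1.20 ± 0.23) and Cxcl9 (0.83 ± 0.21) were higher and 0 lower, and that list did not pass. Ifnb1 (0.81 ± 0.15) and Irf1 (0.44 ± 0.12, adjusted p = 0.0487) were higher, while Il1b (0.29 ± 0.14, 0.282), Il10 (-0.31 ± 0.16, 0.306), Nos2 (-0.25 ± 0.18, 0.487), Cxcl10 (0.05 ± 0.28, 0.951) and Atf3 (0.21 ± 0.16, 0.520) did not pass. The limits given for Cxcl10 under HDL hold here too. NRF2 oxidative stress genes were higher in 5 of 16 cases and lower in 1, and in 7 and 1 adjusted over the list alone (median 0.26, camera adjusted p = 0.000623, and 0.0300 with an estimated correlation), with Slc7a11, Gsta3 (1.31 ± 0.13) and the glutathione synthesis gene Gclm (1.09 ± 0.15) higher and Osgin1 at least 1.67-fold lower. The cyclodextrin arrays detected 34.3 ± 0.963% of probes and the PBS LPS arrays 36.7 ± 0.265%.

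Cell cycle genes were lower under cyclodextrin in 6 of 20 cases and higher in 0, and 10 were lower and 1 higher adjusted over the list alone (median -0.41, camera adjusted p = 4.49e-07, and 0.0150 with an estimated correlation). Among them were Cdc20 (-1.18 ± 0.15), Aurkb (-0.90 ± 0.11), Plk1 (-0.90 ± 0.15) and Aurka (-0.81 ± 0.13). Cholesterol synthesis genes were lower in 3 of 18 cases, and in 7 adjusted over the list alone (median -0.40, camera adjusted p = 8.15e-06, and 0.0407 with an estimated correlation). These 3 were Lss (-0.70 ± 0.14, with its other probe higher at 0.54), Sc5d (-0.59 ± 0.13) and Fdps (-0.56 ± 0.11). Fatty acid synthesis genes were lower in 3 of 13 cases, and in 5 adjusted over the list alone (median -0.29, camera adjusted p = 7.55e-05, and 0.0452 with an estimated correlation). These were Elovl6, at least 1.61-fold lower, Scd2 (-1.11 ± 0.24) and Fads2 (-0.59 ± 0.14). Abcg1 was lower (-0.76 ± 0.18), while Insig1 (0.02 ± 0.15, adjusted p = 0.951) and Srebf2 (-0.01 ± 0.14, 0.979) did not pass. Glycolysis and hypoxia genes were lower in 2 of 15 cases, Ndrg1 (-0.99 ± 0.10) and Pdk1 (-0.53 ± 0.12), and in 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.000781, and 0.0452 with an estimated correlation). Fewer probes were detected on the cyclodextrin arrays (34.3 ± 0.963%) than on the PBS LPS arrays (36.7 ± 0.265%).

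Lists for 3 further groups were lower by camera but not with an estimated correlation. Dendritic cell genes were lower in 3 of 5 cases, Itgae (at least 1.35-fold), Fscn1 (-0.71 ± 0.16) and Batf3 (-0.69 ± 0.13), and in 5 adjusted over the list alone (median -0.69, or -0.43 with genes at their bound, camera adjusted p = 7.55e-05, but adjusted p = 0.0611 with an estimated correlation). Anti-inflammatory genes were lower in 4 of 15 cases, among them the receptor gene Il4ra (-1.24 ± 0.21) and the phosphatase gene Dusp1 (-0.40 ± 0.10), and in 5 adjusted over the list alone (median -0.27, or -0.22 with genes at their bound, 0.00906, but adjusted p = 0.194 with an estimated correlation). Macrophage identity genes had 0 of 14 called and 3 lower adjusted over the list alone, with Maf at -0.70 ± 0.20 (median -0.30, 0.00906, but adjusted p = 0.0611 with an estimated correlation). The cyclodextrin arrays detected 34.3 ± 0.963% of probes against 36.7 ± 0.265% on the PBS LPS arrays. The other 16 tested lists did not pass (adjusted p from 0.0675 to 0.907), though the NF-kB feedback list was called in 7 of 26 settings. Called members in them included the transcription factors Klf4 (1.29 ± 0.18), Egr2 (0.90 ± 0.14) and Rel (0.71 ± 0.10), the cathepsin Ctsl (0.80 ± 0.13) and the chaperone Hspa1a (0.58 ± 0.14). The scavenger receptor Stab1 (-1.05 ± 0.13), Hp (-0.84 ± 0.20), Ptges (-0.77 ± 0.14) and Lcn2 (-0.69 ± 0.15) were lower. Of the 12 genes in the lists too short to test, Dcn was called (at least 1.24-fold lower).

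**Figure D2:**
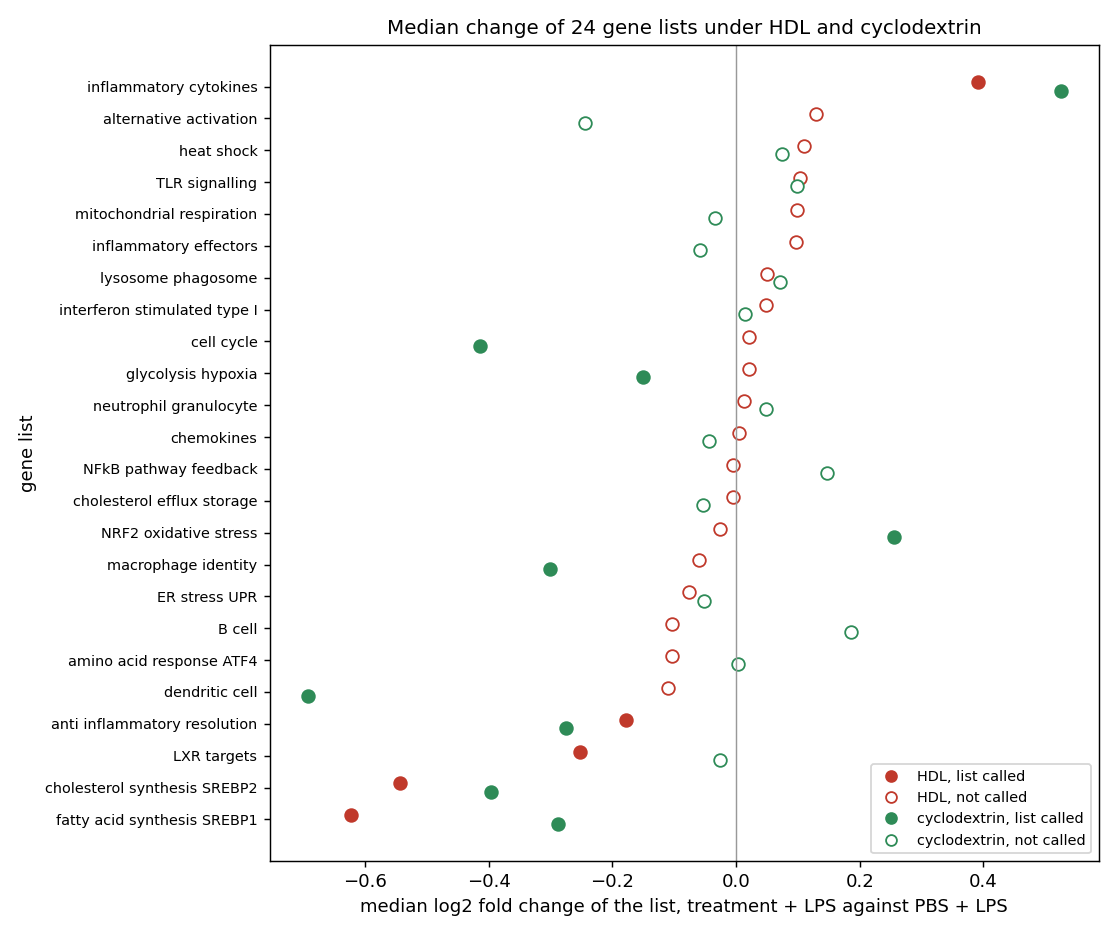
Median log2 fold change of 24 of the 25 tested gene lists under HDL (red) and cyclodextrin (green), each with LPS against PBS with LPS, with filled points for lists called by camera at the preset correlation. The inflammatory cytokine list lay at 0.39 under HDL and 0.53 under cyclodextrin, the cholesterol synthesis list at -0.54 and -0.40, and the cell cycle list at 0.02 and -0.41.

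In all, 497 genes were called between cyclodextrin and PBS, 232 higher and 265 lower (261 and 212 after median scaling), and 29 and 32 of them changed at least 2-fold. Simulated unchanged cyclodextrin groups gave at most 1 call in 100 draws, but HDL groups simulated in the same way reached 956. The cyclodextrin and PBS LPS groups did not overlap in 26.5% of genes, against 10% by chance. The count fell to 229, 250 and 317 without PBS LPS replicates 7, 8 and 9 and to 304 and 265 without cyclodextrin replicates 22 and 24. It was 925 with array weights and 78 with the share of detected probes as a covariate, a fit chosen after seeing the data. The share did not overlap between cyclodextrin and PBS LPS arrays, so this covariate cannot be separated from the treatment. A call lost with it does not show that the share was its cause. In that fit 39 of the 56 called genes named by the rule lost their call, Il6 among them (1.39, adjusted p = 0.0524), and the cytokine, NRF2, cell cycle, sterol and fatty acid lists kept theirs (adjusted p up to 0.00291), while the glycolysis, anti-inflammatory and macrophage identity lists lost theirs (0.200, 0.599 and 0.513). Of the 56 named calls, 26 ended without at least 1 array, among them Tnf in 9 of 12 omissions (adjusted p up to 0.127) and Irf1 in 10 (0.163). Of 19 such genes with several probes, 4 had all of them called, with another probe of Kifc1 at -0.12 and of Cdc20 at -0.22.

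Directly compared, cyclodextrin-treated cells held more Scd1 than HDL-treated cells, 16.2-fold (log2 difference 4.02 ± 0.16, adjusted p = 3.72e-09), more Cdkn1c, 4.07-fold (2.02 ± 0.13), and more Pdzk1ip1 (1.19 ± 0.12), Klk1b11 (1.14 ± 0.13) and Foxa1 (at least 1.52-fold). They held less Ccl17, 3.83-fold (-1.94 ± 0.19), less Fscn1, 2.94-fold (-1.55 ± 0.16), and less Serpinb1a (at least 2.39-fold), Csta2 (at least 1.93-fold) and Cstdc4 (at least 2.08-fold), the last 3 detected on 2, 1 and 1 of 3 cyclodextrin arrays. The doses and times of the 2 treatments differ, so compound and time cannot be told apart in this comparison. Cell cycle genes were lower with cyclodextrin than with HDL in 5 of 20 cases, and in 12 adjusted over the list alone, with 1 higher (median -0.40, camera adjusted p = 7.86e-07, and 0.0293 with an estimated correlation). Among the lower ones were Top2a (-1.14 ± 0.20), Mcm3 (-1.07 ± 0.18) and Aurka (-0.72 ± 0.13). Top2a and Mcm3 were not called under HDL, but lay higher on every HDL array than on every PBS LPS array. Probes were detected in 34.3 ± 0.963% of cases on the cyclodextrin arrays and 36.0 ± 0.173% on the HDL arrays. The cell cycle was the only list that kept its call with an estimated correlation.

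Lists for 9 further groups differed by camera but not with an estimated correlation, with counts here over all genes first and then adjusted over the list alone. Fatty acid synthesis genes were higher with cyclodextrin in 3 of 13 cases, then 4, with Fads2 at 1.14 ± 0.14 and Acss2 at 0.76 ± 0.15 (adjusted p = 0.000212, but adjusted p = 0.0699 with an estimated correlation). Cholesterol synthesis genes were higher in 1 of 18, then 2, with Tm7sf2 at 1.11 ± 0.13 (0.00121, but adjusted p = 0.105 with an estimated correlation). NRF2 genes were higher in 4 of 16, then 7, with Gclm at 1.08 ± 0.15 and Slc7a11 at 0.92 ± 0.17 (0.00121, but adjusted p = 0.0539 with an estimated correlation). LXR targets were higher in 2 of 10, then 4, with Scd1 and Apoe (0.49 ± 0.12), and lower in 1, Nr1h3 at -0.53 ± 0.13 (0.0174, but adjusted p = 0.236 with an estimated correlation). The median of the LXR targets was only 0.079 against a mean of 0.497, with Scd1 alone at 4.02, so their typical member hardly differed. ATF4 genes were higher in 3 of 17, then 4, with the serine synthesis gene Phgdh at 0.95 ± 0.17 and Asns at 0.60 ± 0.12 (0.0229, but adjusted p = 0.305 with an estimated correlation), and this call ended in 5 of 26 settings.

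Lower with cyclodextrin than with HDL were alternative activation genes in 3 of 13 cases, then 7 with 2 higher, among them Stab1 (-0.72 ± 0.13) and Mgl2 (-0.69 ± 0.15) (adjusted p = 0.00213, but adjusted p = 0.0699 with an estimated correlation). Dendritic cell genes were lower in 3 of 5, then 4, with Fscn1 and Batf3 (-0.57 ± 0.13) (0.00121, but adjusted p = 0.120 with an estimated correlation). Glycolysis genes were lower in 1 of 15, then 3, with Pgk1 at -0.56 ± 0.10 (0.00210, but adjusted p = 0.0701 with an estimated correlation). Macrophage identity genes were lower in 1 of 14, then 3, with Itgam at -0.57 ± 0.14 (0.0465, but adjusted p = 0.149 with an estimated correlation), and this call ended in 12 of 26 settings (adjusted p up to 0.391). Other probes of Stab1, of the glutathione transferase Gstm1 (0.72 ± 0.09) and of Pgk1 lay on the other side of 0, at 0.10, -0.16 and 0.15. The other 15 tested lists did not pass (adjusted p from 0.0765 to 0.912). The inflammatory cytokine list was among them, with 0 of 16 genes called and a median of 0.17 (adjusted p = 0.0814). Il6 was at 0.51 ± 0.18 (adjusted p = 0.146), Il12a at 0.49 ± 0.17 (0.138), Tnf at 0.25 ± 0.16 (0.441) and Ifnb1 at 0.49 ± 0.15 (0.108), so none passed. Chemokines were lower in 3 of 16 cases, Ccl17, Pf4 (-0.59 ± 0.13) and Ccl12 (-0.43 ± 0.10), and higher in 0. In the 5 lists too short to test, Pf4 and Dcn (at least 1.27-fold lower) were called.

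In all, 271 genes differed between the treatments, 121 higher and 150 lower with cyclodextrin, and 149 higher and 116 lower after median scaling. At least 2-fold, 13 were higher and 17 lower, and the 2 groups did not overlap in 24.4% of genes, against 10% by chance. The count fell to 130 and 126 without HDL replicates 16 and 18 and to 173, 130 and 140 without cyclodextrin replicates 22, 23 and 24. It was 75 with only the 2 groups in the model, 424 with array weights and 38 with the share of detected probes as a covariate. The fit with that covariate also ended the calls of the ATF4, glycolysis and macrophage identity lists (camera adjusted p = 0.0588, 0.0588 and 0.391). Here too the share did not overlap between the groups, so it cannot be separated from the treatment. Of the 42 named calls, 23 ended without at least 1 array, among them Nr1h3 and Ccl12 in 10 of 12 omissions (adjusted p up to 0.151 and 0.108). Of 16 such genes with several probes, 0 had all of them called, with another probe of Fads2 at 0.0063 and of Top2a at -0.046.

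Under HDL and cyclodextrin, 80 genes were called in the same direction. Of the 186 and 497 genes called, 34 were higher under both treatments and 46 lower under both, against 1.85 and 2.92 for independent lists and means of 0.01 and 0 in simulated unchanged groups that share the PBS LPS arrays. In the simulated groups any gene was called under HDL in only 2 of 100 draws and under cyclodextrin in 1. Their means therefore do not show how far sharing those arrays raises the overlap of 186 and 497 calls. Only Fscn1 (0.84 under HDL, -0.71 under cyclodextrin) and Pdzk1ip1 (-0.73 under HDL, 0.47 under cyclodextrin) were called in opposite directions. Across genes, which are not independent replicates, the fold changes had a covariance of 0.0348 against 0.0119 (-0.0155 to 0.0505) in the simulated groups, and r = 0.509 against 0.447 (-0.626 to 0.953), and 4 of 100 draws reached the observed covariance and 50 of 100 the observed r. The 3 PBS LPS arrays cannot be split, and part of the excess may come from sharing them. Of 104 genes called under HDL alone, 31 differed between the treatments when tested directly, and of 415 called under cyclodextrin alone, 117 did. In the simulated groups the calls under HDL alone had a mean of 14.4 and reached 956, with at least 104 in 2 of 100 draws. Those under cyclodextrin alone were 0 in every draw. Both groups were simulated in the same way, so the 956 holds for cyclodextrin too, and the 415 lies below it. The 80 shared calls fell to 16, 18 and 46 without PBS LPS replicates 7, 8 and 9, to 32, 30 and 33 without HDL replicates 16, 17 and 18, to 45 and 49 without cyclodextrin replicates 22 and 24 and to 48 without PBS replicate 3. They were 35 with only the 2 groups of each comparison in the model.

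The genes that LPS changed at least 2-fold had small median shifts under the treatments. The 1058 induced genes had a median log2 fold change of 0.055 under HDL (simulated -0.065 to 0.029) and 0.064 under cyclodextrin (-0.060 to 0.023), and the 1196 repressed genes of -0.058 under HDL (-0.041 to 0.105) and -0.092 under cyclodextrin (-0.048 to 0.086). Among the induced genes, 30 were higher and 15 lower under HDL, and 74 higher and 42 lower under cyclodextrin. Among the repressed genes, 8 were higher and 40 lower under HDL, and 28 higher and 116 lower under cyclodextrin. The simulated HDL counts reached 51 and 55 among the induced and 79 and 38 among the repressed genes. Of the HDL counts only the 40 lay above them. The simulated cyclodextrin counts were 0 in every draw. Both treated groups were simulated in the same way, so the ranges for HDL hold for cyclodextrin too. Against these ranges the 74 and 116 under cyclodextrin lay above, and the 42 and 28 within. With the share of detected probes as a covariate the cyclodextrin medians were 0.110 and -0.162. With median scaling the induced median under HDL was 0.0294 and the repressed median under cyclodextrin -0.0498, next to the limits of the simulated groups. No array with a treatment but without LPS was analysed here, so an effect on the LPS response cannot be told apart from an effect present without LPS. In the 2072 genes left when values placed by the array curve were dropped, a check chosen after seeing the data, the median of the repressed genes under cyclodextrin stayed at -0.061 and the other 3 had the opposite sign (-0.037 and -0.051 for induced genes under HDL and cyclodextrin, 0.0076 for repressed genes under HDL). The signs were the same in those genes with all values kept.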

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

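The tests of decimal places, of normalization and of a single control array below were chosen after the results they bear on had been seen.

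Probes that are not listed with a single gene were left out of the comparisons of genes, so their signal is data outside the main measurement. Of 2867 such probes above background, 1380 were called under LPS (631 higher, 749 lower; 48.1% against 57.4% of probes with a gene), 27 under HDL (7 higher, 20 lower; 0.942% against 0.845%), 103 under cyclodextrin (51 higher, 52 lower) and 41 between cyclodextrin and HDL (23 higher, 18 lower). Fscn1 and Pdzk1ip1 differ between the treatments and were called in opposite directions under them. The log2 difference of cyclodextrin minus HDL, tested directly, was -1.55 for Fscn1 and 1.19 for Pdzk1ip1.

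Fatty acid synthesis genes were lower under HDL (median log2 fold change -0.62). A misplaced decimal mark would move a non-normalized signal by 3.32 on the log2 scale. The largest SD within a group among the called genes of the list was 0.348, which argues against wrong places on part of a group's arrays. The SD cannot show a place set wrongly on all 3 arrays of a group. The change of Scd1 (-3.94) is larger than 3.32, so this is not decided for Scd1. The next largest change in the list, Fads2 at -1.73, is smaller than such a move. Scd1, with the largest change, had its place set without the array curve on 3 of 3 PBS LPS and 2 of 3 HDL arrays. Where these places came from the detection p-value or the number of digits, the test with hidden values did not cover them. The tables also argue against the normalization, since the weakest median over 5 other scalings was -0.55. An effect of HDL on these genes stays open as a hypothesis, found and tested on the same arrays.

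Cell cycle genes were lower under cyclodextrin (median -0.41). The cyclodextrin arrays detected fewer probes, but among 10000 random lists matched on level the median lay at percentile 0 (random lists -0.109 to 0.115), against a lower signal over background as the whole cause. Against a larger response to LPS as a whole, it lay at percentile 0.03 among lists matched on the LPS fold change (-0.256 to 0.0185), whose own median was -0.11, so part of the shift is shared with genes that LPS lowers. An effect of cyclodextrin on dividing cells, or on how many cells divide, stays open as a hypothesis, found and tested on the same arrays.

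Inflammatory cytokines were higher under both treatments (medians 0.39 and 0.53). Against a larger response to LPS as a whole, both medians lay at percentile 100 among lists matched on the LPS fold change (-0.0919 to 0.190 for HDL, -0.0912 to 0.200 for cyclodextrin). The match was made in bins of rank, which is coarse among the genes that LPS raised most. It shows only that other genes of those bins did not rise as far. Against a single low PBS LPS array, the lowest median without each of the 3 was 0.353. Sharing the 3 PBS LPS arrays links the 2 comparisons and cannot be undone here. An effect of both treatments on these genes stays open as a hypothesis, found and tested on the same arrays.

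The 6 arrays of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5932 genes for LPS, 186 for HDL, 497 for cyclodextrin and 271 for cyclodextrin minus HDL, and 0 was the highest of the other splits each time. For gene lists, the real split gave 11 for LPS, 5 for HDL, 9 for cyclodextrin and 10 for cyclodextrin minus HDL, and the highest of the other splits gave 12, 9, 7 and 6. Every other split keeps part of the difference between the groups and puts the rest into the spread within groups. Neither its 0 genes nor its lists are therefore a measure of chance.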

How the results depend on the processing

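A gene or list counts as reversed here only where it was called in 1 of the 2 fits. No list reversed in any setting. The alternatives on decimal places and on the share of detected probes were chosen after seeing the data. Of these, the fit of only genes with no value placed by the array curve was run first, and the fit leaving out such values was added after its result was seen. A fit with slide as a block was not run, because the files name no slides. The detected share did not overlap between the groups with LPS, so a fit with it as a covariate cannot separate it from the treatments. Signal over background limits what dim genes can show. Where nothing else is said, the cause was not tested.

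With every probe on its own, 10276 of 18364 probes were called for LPS, those without a gene included. The genes changed by LPS numbered 2254 with a fold change of at least 2, 509 with values placed by the array curve left out and 329 with only genes with no such value (fewer genes tested in both). Those changed by HDL numbered 283 with no background correction, 282 with normexp, 102 with no detection filter (more genes tested), 80 with only the 2 groups compared (fewer arrays), 575 with array weights, 20 at 2-fold, 7 with curve values left out and 9 with only genes without them. For cyclodextrin they numbered 925 with array weights, 61 at 2-fold, 78 with the detected share as a covariate, 38 with curve values left out and 31 with only genes without them. Between cyclodextrin and HDL they numbered 75 with only the 2 groups compared, 424 with array weights, 30 at 2-fold, 38 with the detected share as a covariate, 18 with curve values left out and 13 with only genes without them. The shared calls numbered 45 with no detection filter, 35 with only the 2 groups compared, 227 with array weights, 10 at 2-fold, 34 with the detected share as a covariate, 4 with curve values left out and 5 with only genes without them. Array weights ran from 0.369 to 4.86.

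Leaving out values placed by the curve kept 2072 of 9795 genes. In these same genes, the fits without and with such values called 509 and 531 for LPS (503 in both), 7 and 7 for HDL, 38 and 38 for cyclodextrin and 18 and 19 for cyclodextrin minus HDL, so the lower counts come with the genes left. The genes with no such value number 1667, with a median level of 5.34 against 8.20 for all, and only 3 lists could be tested in them, of which 1 was called for LPS, 0 for HDL, 0 for cyclodextrin and 0 for cyclodextrin minus HDL.

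The median of LPS-induced genes under HDL was 0.0639 with cyclic loess, 0.0294 with median scaling and 0.0644 with the detected share as a covariate, and it turned to -0.037 with curve values left out and -0.070 with only genes without them. Under cyclodextrin it was 0.110 with the covariate and turned to -0.051 and -0.093. The median of LPS-repressed genes under HDL turned to 0.0076 and 0.037, and under cyclodextrin it was -0.0498 with median scaling, -0.162 with the covariate, -0.061 with curve values left out and -0.031 with only genes without them. The fit with curve values left out called 83 induced and 52 repressed genes anew. The same genes fitted with all values gave 84 induced and 59 repressed ones, with medians of -0.012 and -0.043 for induced and 0.0045 and -0.058 for repressed genes under HDL and cyclodextrin. Of the 1058 induced and 1196 repressed genes, 55 and 14 have no value placed by the curve.

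The lists called numbered 3 for HDL and 1 for cyclodextrin minus HDL with an estimated correlation and 21 for LPS with fry. With the detected share as a covariate, the anti-inflammatory list lost its call under HDL (adjusted p = 0.239), the glycolysis, anti-inflammatory and macrophage identity lists lost theirs under cyclodextrin (0.200, 0.599 and 0.513), the ATF4, glycolysis and macrophage identity lists lost their call between cyclodextrin and HDL (0.0588, 0.0588 and 0.391), and the NF-kB list gained 1 under cyclodextrin (0.000521) and between cyclodextrin and HDL (0.000884). The macrophage identity list lost its call between cyclodextrin and HDL in 12 of 26 settings, which were median scaling, the stricter detection filter, the mean of probes, only the 2 groups compared, array weights, an estimated correlation, the detected share, and the fits without PBS replicate 1 or 2, HDL replicate 18 or cyclodextrin replicate 22 or 23. Under LPS, 3 named genes turned, Cox4i1 to 0.059 and Pf4 to 0.46 with median scaling, and Insig1 to 0.071 with the mean of probes. Counts of higher or lower genes moved by over 1.5 times in 45 of 128 values with all arrays and in 33 of 96 with 1 array left out.

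With 1 array left out, the genes changed ran from 5441 to 5972 for LPS, 36 to 223 for HDL, 229 to 599 for cyclodextrin and 126 to 368 for cyclodextrin minus HDL, and the shared calls from 16 to 94. The induced median ran from 0.0475 to 0.0597 under HDL and 0.0443 to 0.0905 under cyclodextrin, the repressed median from -0.0816 to -0.0411 and -0.101 to -0.0776. Lists called stayed at 11 for LPS and ran from 3 to 5 for HDL (3 without HDL replicate 17), 8 to 11 for cyclodextrin and 8 to 11 for cyclodextrin minus HDL. Of the called genes named by the rule, 109 of 113 for LPS, 12 of 29 for HDL, 30 of 56 for cyclodextrin and 19 of 42 for cyclodextrin minus HDL kept their call without each array.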
